A study of Homo sapiens with 24 samples.

How the data were processed

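RNA-seq of poly(A)-selected RNA was analysed for 24 libraries of the human induced pluripotent stem cell line FSPS13b, with an unmodified (wild-type) genotype per the labels, at 8 days of a differentiation toward pancreatic endocrine cells (days 0, 3, 6, 9, 12, 15, 18 and 24, 3 libraries per day). Total RNA was extracted with a column kit and the libraries were made with an unstranded kit, per the labels' protocols. Raw counts of read pairs per gene were deposited for every library. They were made by the authors with featureCounts 1.4.4 against an Ensembl GRCh37 gene annotation, counting pairs with both ends aligned and leaving out chimeric pairs, with no strand option, per the file headers. The submitters' processing notes name the builds hg19 and GRCh37 and the tool edgeR. The aligner is not given in the sources used here. Because strand was not recorded, reads of a gene and of an overlapping antisense gene cannot be separated, and genes with close copies elsewhere in the genome may lose reads or share them.

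RPKM values for the same libraries were also deposited by the authors. Each equalled the count divided by the gene length and by a library size that matched the TMM-scaled size recomputed here (ratio 1 at the lowest and the highest), which differed from the raw total by a factor of 0.833 to 1.09. The deposited counts were used for the main tests, and the deposited RPKM values only for an alternative. All columns belonged to a library of the series.

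The count table held 56299 genes by Ensembl identifier, of which 37317 (66.3%) were given a symbol by matching the identifier to a later gene annotation. That annotation was used for names alone, since its build differs from GRCh37, and all coordinates are those of the count table. The total count ranged from 8700062 (Day 0 replicate 2) to 120341031 (Day 6 replicate 3). A floor of 3 counts per library corresponded to 0.0249 to 0.345 CPM, counts scaled to a common library size. Intervals and floors cover counting error only. No pair of the 24 pairs of libraries of the same day held identical values. Their Pearson correlations across genes on log2 CPM were 0.992 to 0.998 (genes are not independent replicates), and their chi-square per degree of freedom was 4.68 to 121, so all pairs differed by more than sampling noise and each library counted as 1 replicate.

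Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by day, which left 21429 genes holding 99.958% of all counts, and libraries were scaled with TMM. Quasi-likelihood models (robust glmQLFit, glmQLFTest) were fitted over all 24 libraries with the day as the group, so that all days shared an estimate of the spread. The common biological coefficient of variation was 0.104. Each day was compared with the day sampled before it, day 24 was compared with day 0, and an F test asked whether a gene differed over the 8 days. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and adjusted p-values under 0.05 were called. CPM values are on the TMM-scaled library sizes. The median log2 change over all tested genes lay between -0.03 and 0.09 in the 8 comparisons.

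The samples, the tests, the named-gene rule, the gene lists and the alternatives were fixed before the data were examined. In each comparison the rule took NEUROG3 and HES1, the 5 largest rises and 5 largest falls among called genes with a mean of at least 10 CPM on the higher day and ranges that did not overlap between the days, the 4 called members with the largest change from each list assigned to that comparison, and up to 2 called members of other lists. Over the 8 days it took NEUROG3, HES1, POU5F1, SOX17, PDX1, NKX6-1, PTF1A, NEUROD1, PAX4, INS, GCG, SST and CHGA. Some genes that the rule took are not reported here. Genes named outside the rule are said to have been chosen after their values were seen. The 29 lists (314 genes) were pluripotency, primitive streak, definitive endoderm, gut tube, pancreatic progenitor, endocrine progenitor, islet transcription factors, islet hormones, secretory granule, glucose sensing and beta cell function, acinar, ductal, Notch pathway, enterochromaffin, liver, intestine and stomach, mesenchyme, endothelium and blood, neural, cell cycle, CDK inhibitors, Nodal signalling, WNT signalling targets, hedgehog signalling, retinoic acid response, ER stress, hypoxia and glycolysis, oxidative phosphorylation, and mitochondrially encoded genes. LHX1 was not matched by name and PPY, IAPP, G6PC2, CTRC, PNLIP, AMY2A, CTRB1, CDX1, MUC2, GKN1, PECAM1 and PTPRC fell below the count filter, so these were not tested.

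Each list was tested against the other genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 232 pairs of list and comparison. Members were also counted after adjustment over the list alone. Of the 232 pairs, 112 passed camera, and 41 of these 112 also passed with a correlation estimated from the data. The rotation test fry, which asks whether a list's genes moved 1 way on balance and does not compare them with other genes, passed for 179. Folds against a day with 0 counts in all its libraries are lower bounds computed at 3 counts per library. Where the lower day had 1 to 3 counts in all, the ratio of the pooled count rates (the counts of a day summed over its libraries, divided by their summed TMM-scaled sizes) is given with an exact 95% counting interval; it differs from the ratio of the mean CPM values.

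The alternatives were DESeq2 size factors in the edgeR fit, no count filter, the DESeq2 1.42.0 test, the replicate number as a block, a change of at least 2-fold beside the adjusted p, limma on log2(RPKM + 1) and log2(RPKM + 0.1), a fit of only the 6 libraries of the days compared, each library left out in turn, camera with an estimated correlation, and fry. For a list, the lowest and highest adjusted p over the alternatives are at the preset correlation. They cover DESeq2 size factors, no count filter, the replicate block and each library left out. For a named gene they leave out the 2-fold rule and the fit of only the 6 libraries, which was not applied to named genes. The edgeR procedure was tested on simulated counts with the means and library sizes of day 24 against day 18 (21429 genes, 200 changed). It recovered 25 of 50 genes raised 1.5-fold, 39 of 50 raised 2-fold, 47 of 50 raised 4-fold and 31 of 50 lowered to 0.5-fold. It made 149 calls, 7 of them false (4.70%). The simulated spread of a gene was the fitted one and was the same on all days. This simulation therefore cannot show errors that arise where the spread differs between days.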

Results

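Gene expression was measured by RNA-seq in the human induced pluripotent stem cell line FSPS13b while it was differentiated toward endocrine cells of the pancreas, with the timing of NEUROG3 (also called NGN3) as the subject of the study. The 24 libraries comprised 3 on each of days 0, 3, 6, 9, 12, 15, 18 and 24. Their total counts ran from 8700062 (Day 0 replicate 2) to 120341031 (Day 6 replicate 3). The labels call the libraries of a day biological replicates but do not say how their cultures were separate, so the p-values measure the spread between these samples. Levels below are mean CPM (counts scaled to a common library size) ± SD with n = 3 libraries per day, and changes are log2 fold changes of the later against the earlier day ± standard error, with adjusted p from the quasi-likelihood test of edgeR. Genes given as the exceptions within a list were chosen after their values were seen.

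NEUROG3, the transcription factor that starts the endocrine program in the pancreas (ENSG00000122859, chromosome 10, 71331454 to 71332994, minus strand, GRCh37), was at 1.21 ± 0.0243 CPM on day 0, at 0 counts on day 3 and at 0.0861 ± 0.0423 CPM on day 6. It then stood at 39.9 ± 0.0732 CPM on day 9, 30.9 ± 5.67 on day 12, 69.4 ± 12.07 on day 15, 19.6 ± 1.82 on day 18 and 11.5 ± 1.83 on day 24. On day 0 (157 counts) and day 9 (7920 counts) the SD was below what counting error alone would give, so it understates the uncertainty. The rise from day 6 to day 9 was 8.91 ± 0.24 on the log2 scale (edgeR adjusted p = 8.7e-18), the rise from day 12 to day 15 was 1.17 ± 0.14 (6.8e-07), and the fall from day 15 to day 18 was -1.83 ± 0.14 (3.2e-09). A further fall to day 24 was -0.77 ± 0.14 (4.2e-04). Between day 9 and day 12 the change was -0.37 ± 0.13 (edgeR adjusted p = 0.0343). That call ended with DESeq2 size factors (-0.34, adjusted p = 0.0535) and without any of 5 libraries: 0.0705, 0.0753 and 0.0732 without Day 9 replicate 1, 2 or 3, 0.184 without Day 12 replicate 2 and 0.068 without Day 12 replicate 3. Over its 12 alternatives the adjusted p ran from 4.6e-04 to 0.184.

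HES1, a Notch target that represses NEUROG3 (ENSG00000114315, chromosome 3, 193853934 to 193856521, plus strand), fell from 29.1 ± 4.28 CPM on day 0 to 8.70 ± 0.674 on day 3 and rose to 49.3 ± 0.953 on day 6 and 142 ± 3.14 on day 9. It was at 150 ± 6.17 CPM on day 12, 105 ± 6.09 on day 15, 139 ± 12.22 on day 18 and 122 ± 6.66 on day 24. HES1 and NEUROG3 both fell from day 0 to day 3 and both rose from day 3 to day 6 and from day 6 to day 9. In the last of these steps HES1 rose by 1.53 ± 0.07 (edgeR adjusted p = 1.9e-15) and NEUROG3 by 8.91 ± 0.24 (8.7e-18). The fall of HES1 from day 12 to day 15, the step in which NEUROG3 rose, was -0.51 ± 0.07 (edgeR adjusted p = 3.7e-06). Its rise from day 15 to day 18, in which NEUROG3 fell, was 0.40 ± 0.07 (1.7e-04). The change from day 9 to day 12 was 0.07 ± 0.07 (0.445) and that from day 18 to day 24 was -0.19 ± 0.07 (0.057). The latter passed the test with DESeq2 size factors (0.0247), with DESeq2 (0.0119), without Day 18 replicate 1 (0.0264) and without Day 24 replicate 2 (0.0475), and ran from 0.0119 to 0.288 over its alternatives.

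**Figure D1:**
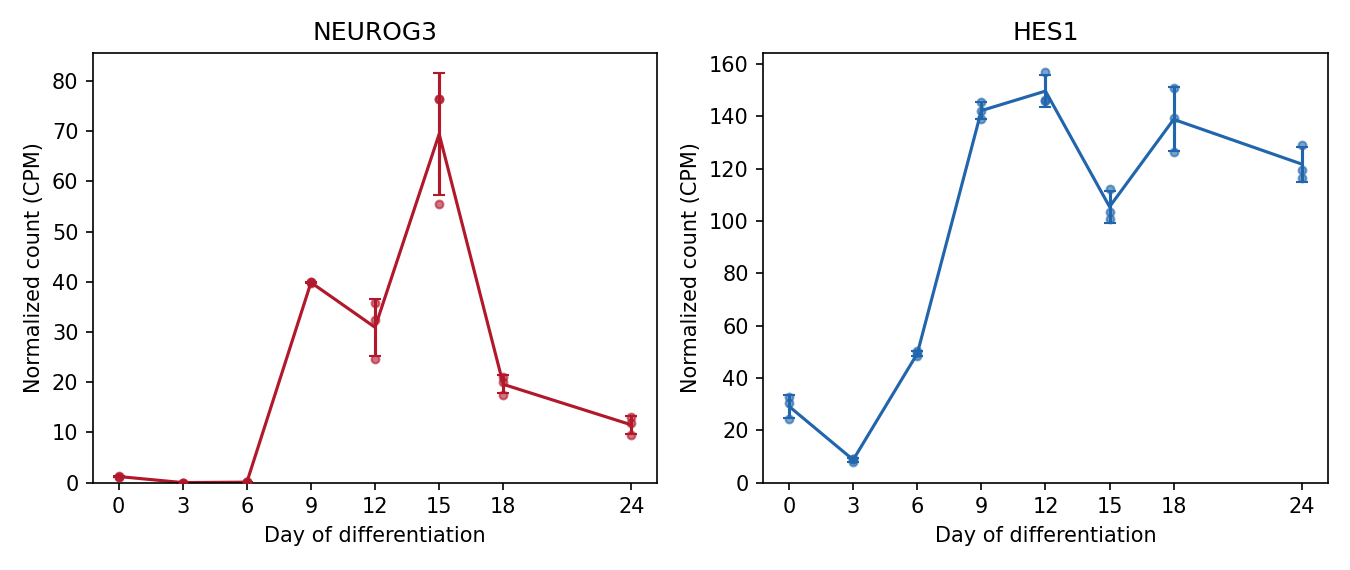
Normalized counts, as CPM (y axis) of NEUROG3 (left) and HES1 (right) against the day of differentiation (x axis); points are single libraries and the line with bars is the mean ± SD of 3 libraries. NEUROG3 was highest on day 15 (69.4 CPM), the day on which HES1 was at 105 CPM, below its means of 150 CPM on day 12 and 139 CPM on day 18. Both genes rose from day 6 to day 9.

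The other genes followed over the 8 days reached their highest means on days 0, 3, 15, 18 and 24. POU5F1, a pluripotency factor (chromosome 6, 31130253 to 31148508), was highest on day 0 at 1568 ± 84.2 CPM, and SOX17, a factor of definitive endoderm (chromosome 8, 55370495 to 55373448), on day 3 at 517 ± 60.5 CPM. PDX1, required for pancreas formation, was highest on day 15 at 153 ± 13.0 CPM, as were NEUROD1 (62.8 ± 4.25), a direct target of NEUROG3, and PAX4 (15.0 ± 2.93), which favours the beta cell fate. NEUROD1 was no clear peak, at 59.3 ± 6.00 CPM on day 18 (edgeR adjusted p = 0.608 against day 15) and 56.1 ± 9.56 on day 24 (0.596 against day 18). NKX6-1, a beta cell factor, was highest on day 24 at 11.8 ± 1.51 CPM, and PTF1A, a factor of pancreatic progenitors and acinar cells, reached at most 1.26 ± 0.373 CPM, on day 18. PTF1A on day 18 did not differ past the test from day 15 (edgeR adjusted p = 0.0815) or day 24 (0.325). The hormones insulin (INS, chromosome 11, 2181009 to 2182571), glucagon (GCG) and somatostatin (SST) and the granule protein CHGA (chromosome 14, 93389425 to 93401638) were highest on day 24, at 412 ± 50.2, 1914 ± 323, 31.3 ± 6.78 and 9418 ± 1681 CPM. All of these genes changed over the 8 days (edgeR F test, largest adjusted p = 6.0e-13, for PTF1A), as did 20246 of the 21429 genes tested. Among the genes that changed over the 8 days, the highest mean fell on day 0 for 4639 genes, on day 3 for 3991, on day 6 for 1870, on day 9 for 1828, on day 12 for 903, on day 15 for 2320, on day 18 for 1371 and on day 24 for 3324.

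**Figure D2:**
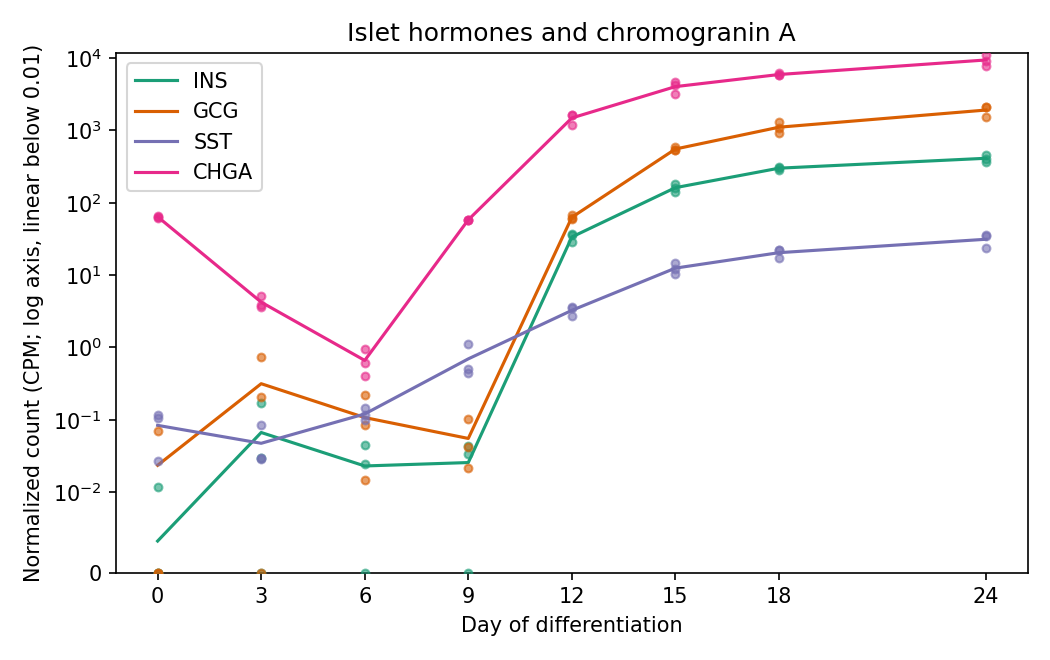
Normalized counts, as CPM (y axis, logarithmic above 0.01 and linear below it) of INS, GCG, SST and CHGA against the day of differentiation (x axis), with points for single libraries and lines through the means of 3 libraries. On day 24 GCG was at 1914 CPM, INS at 412 CPM and SST at 31.3 CPM. CPM is not divided by gene length, so these values do not rank the transcripts of different genes.

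The comparison of day 3 with day 0 covered the exit from pluripotency. The pluripotency factors SOX2 (354 ± 14.6 to 7.33 ± 1.17 CPM), NANOG (56.6 ± 2.80 to 1.10 ± 0.0404) and POU5F1 (1568 ± 84.2 to 34.8 ± 3.24) fell by 47.7-fold, 51.2-fold and 45.1-fold. EOMES, a T-box factor of the primitive streak, rose 54.6-fold from 18.0 ± 1.88 to 962 ± 8.71 CPM, and the homeobox factors GSC and MIXL1 rose 43.5-fold and 15.5-fold. CER1, a secreted antagonist of Nodal, BMP and WNT signals, rose 215-fold to 6406 ± 198 CPM, GATA4 rose 83.8-fold, GATA6 76.9-fold and SOX17 58.5-fold. LEFTY2 and LEFTY1, feedback inhibitors of Nodal, rose 55.6-fold and 8.62-fold, and NODAL itself 4.06-fold, from 14.5 ± 0.804 to 58.9 ± 6.53 CPM.

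Of 12 pluripotency genes, 11 fell and 1, TDGF1, rose (camera adjusted p = 1.5e-14). Of 8 primitive streak genes, 6 rose, FGF4 fell and TBXT did not pass (1.4e-08). All 9 definitive endoderm genes rose (2.9e-32), and of 7 Nodal signalling genes 5 rose, FOXH1 fell and GDF3 did not pass (7.8e-06). The neural list also passed, with 3 genes higher and 7 lower (camera adjusted p = 0.0299; adjusted p = 0.417 with an estimated correlation). In it SOX1 was lower on day 3 by a ratio of 152 (95% counting interval 51.9 to 742, 3 counts on day 3; log2 change -7.16, -7.763 without Day 3 replicate 1). All 7 CDK inhibitor genes rose (0.0151; adjusted p = 0.0861 with an estimated correlation), CDKN2C by 54.8-fold. The counts of these 6 lists were the same when adjusted over the list alone. The largest rises among abundant genes included NPPA, a natriuretic peptide (857-fold, to 47.6 ± 4.07 CPM; log2 change 9.743, 10.92 without Day 0 replicate 1), and PDZRN4 (391-fold). The paralogs GYPB and GYPE also rose, but their counts are uncertain because they share sequence. The largest falls included HES3, a neural progenitor factor of the HES family (632-fold, from 50.4 ± 6.996 CPM), and the microRNA host gene MIR124-1HG (393-fold; log2 change -8.62, -7.951 without Day 3 replicate 1). NEUROG3 fell from 157 counts to 0, at least 16.1-fold. In all, 6658 genes were higher and 7136 lower on day 3 (edgeR adjusted p under 0.05), 64.4% of those tested.

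From day 3 to day 6 primitive streak genes and most definitive endoderm genes fell, and genes of the foregut and liver rose. CER1 fell to 0.888 ± 1.47 CPM (7382-fold; log2 change -12.85, -16.73 without Day 6 replicate 1, which held 175 of its 184 counts on that day, and -12.05 without Day 6 replicate 3), EOMES to 1.51 ± 0.218 (630-fold), MIXL1 159-fold and LEFTY2 924-fold. FOXA1, a pioneer factor of the gut endoderm, rose 45.6-fold from 6.22 ± 1.15 to 288 ± 4.80 CPM, HNF4A rose 9.58-fold, and PDX1 rose 236-fold to 11.7 ± 1.87 CPM. Transthyretin (TTR), a thyroid hormone carrier of liver and islets, rose from 0.199 ± 0.201 to 425 ± 20.3 CPM (2429-fold; log2 change 11.25, 10.58 without Day 3 replicate 1 and 12.42 without Day 3 replicate 3). Keratin 4 (KRT4) and the intestinal homeobox factor ISX rose from 0 counts, at least 673-fold and at least 651-fold.

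All 8 primitive streak genes fell (camera adjusted p = 1.4e-15), as did all 7 Nodal signalling genes (7.9e-13). Of 9 definitive endoderm genes 6 fell, FOXA2 (3.83-fold) and GATA4 rose and FOXQ1 did not pass (0.00735; adjusted p = 0.103 with an estimated correlation). Of 11 gut tube genes 8 rose, KRT18 fell and 2 (PROX1, KRT8) did not pass (4.4e-10). The WNT targets NOTUM, SP5 and LGR5 fell 35.8-fold, 13.3-fold and 11.4-fold. Of the 9 genes of that list 6 fell, 2 (LEF1, RNF43) rose and ZNRF3 did not pass, and the list did not pass camera (0.0943; 0.035 with no count filter). All 12 liver genes rose (7.2e-28). From the retinoic acid response list 6 of 9 genes rose and CYP26A1, which degrades retinoic acid, fell (1.4e-12). IHH, a hedgehog ligand, rose 1304-fold to 115 ± 7.04 CPM. Of 10 intestine and stomach genes 4 rose (CDX2, TFF3, VIL1, CLDN18) and 6 did not pass (2.8e-04). All 13 mitochondrially encoded genes fell (0.0054; adjusted p = 0.474 with an estimated correlation), MT-ND1 by 1.93-fold, and the mitochondrial share of counts went from 4.36% ± 0.247 to 3.19% ± 0.2002. When adjusted over the list alone, 2 retinoic acid response genes were lower, and the counts of the other lists given here did not change. NEUROG3 rose from 0 to 18 counts, at least 1.15-fold, a call that ended with limma on log2(RPKM + 1), adjusted p = 0.564 (2.3e-04 to 0.564 over its alternatives). In all, 7320 genes were higher and 6693 lower on day 6 (edgeR).

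Between day 6 and day 9 NEUROG3 came on together with endocrine genes downstream of it. NEUROG3 rose 483-fold to 39.9 ± 0.0732 CPM, and the secretory granule proteins CHGA and SCG2 rose 92.3-fold and 37.0-fold. CHGA was not new to the cells, at 64.1 ± 2.20 CPM on day 0, 0.663 ± 0.279 on day 6 and 58.1 ± 0.429 on day 9. PAX4 rose from 0 counts to 3.06 ± 0.137 CPM, at least 63.7-fold. PDX1 rose 7.05-fold to 81.6 ± 4.36 CPM, SOX9, a progenitor and duct factor, rose 3.57-fold to 81.5 ± 2.55, and HES1 rose 2.88-fold. The largest rises also took in CPB1, a pancreatic carboxypeptidase (1433-fold to 491 ± 3.72 CPM), and the anion exchanger SLC26A3 (724-fold). The largest falls included the apolipoprotein APOB (24.7-fold, from 121 ± 12.8 CPM) and SOAT2, which esterifies cholesterol (32.8-fold).

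Of 14 endocrine progenitor genes 12 rose and 2 (NHLH1, MYT1) did not pass (camera adjusted p = 6.4e-20). Of 16 secretory granule genes 13 rose, SCG5 and PCSK2 fell and VGF did not pass (2.2e-06; adjusted p = 0.0987 with an estimated correlation). Of 11 gut tube genes 8 rose, led by PROX1 (10.3-fold), ONECUT2 fell and 2 (HNF4G, FOXA3) did not pass (5.2e-08). Of 11 pancreatic progenitor genes 7 rose and 4 (NKX6-1, NKX6-2, GP2, FOXE1) did not pass (4.0e-04; adjusted p = 0.144 with an estimated correlation). The hedgehog list fell, with GLI1 down 34.3-fold, HHIP 12.5-fold and IHH 4.07-fold among 5 of 7 genes, while SHH rose 6.57-fold to 14.3 ± 1.46 CPM and GLI3 did not pass (2.3e-05). In the retinoic acid response list 5 genes fell, among them CYP26A1 by 5.83-fold, and 4 rose (CYP26B1, DHRS3, STRA6, RDH10), and camera did not pass (0.0597). This list passed with the replicate number as a block (0.0144) and without Day 6 replicate 2 (0.0415), Day 9 replicate 3 (0.0421), Day 18 replicate 3 (0.0479), Day 24 replicate 2 (0.0254) or Day 24 replicate 3 (0.0216), and ran up to 0.235 at the preset correlation. Of 6 endothelium and blood genes 5 fell, VWF by 14.3-fold, and HBE1, whose counts are uncertain because its annotated span overlaps other genes, was higher (1.1e-06). The counts of these 7 lists were the same when adjusted over the list alone. In all, 5788 genes were higher and 5356 lower on day 9 (edgeR).

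From day 9 to day 12 hormone genes rose and mitotic genes fell. GCG rose 1194-fold to 63.1 ± 4.24 CPM, INS 1037-fold to 33.7 ± 4.63, ghrelin (GHRL) 25.2-fold to 57.2 ± 7.80, and CHGA 25.6-fold to 1488 ± 274. TH, the rate-limiting enzyme of catecholamine synthesis, rose 106-fold to 22.0 ± 3.81 CPM. The serotonergic factor FEV rose 16.9-fold to 9.43 ± 0.774 CPM and NKX6-1 35.2-fold, to 1.70 ± 0.263 CPM. TOP2A, which untangles DNA in dividing cells, fell 4.47-fold from 918 ± 48.2 to 205 ± 18.9 CPM, the spindle checkpoint kinase BUB1 4.54-fold, and HMMR and DLGAP5, both of the mitotic spindle, 5.74-fold and 5.15-fold. The log2 changes were 10.22 for GCG (10.99 without Day 9 replicate 3), 10.02 for INS (10.63 without Day 9 replicate 2) and 5.138 for NKX6-1 (4.45 without Day 9 replicate 2). NEUROG3 and HES1 in this step are given above.

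Of 5 islet hormone genes tested 4 rose and PYY did not pass (camera adjusted p = 7.0e-19), after 2 had risen and 1 had fallen from day 6 to day 9 (0.489), and of 16 secretory granule genes 14 rose, RAB3B fell and CPE did not pass (2.3e-16). Of 14 endocrine progenitor genes 9 rose, NEUROG3 and RFX6 fell and 3 (INSM1, RFX3, RUNX1T1) did not pass (4.4e-05; adjusted p = 0.0861 with an estimated correlation). Of 11 pancreatic progenitor genes 9 rose and MNX1 and MEIS1 fell (5.9e-04; adjusted p = 0.17 with an estimated correlation). The Notch list had 9 genes higher, MFNG by 2.02-fold and HEYL by 1.79-fold, 2 lower (HEY1, DLL1) and 8 not past, and did not pass camera (0.0614; 0.00157 with no count filter and 0.0308 without Day 12 replicate 2). Of 12 liver genes 7 rose, SERPINA1, a protease inhibitor, by 7.46-fold to 2234 ± 180 CPM, APOA2 fell 3.38-fold and 4 (AFP, APOB, TF, AHSG) did not pass (2.9e-05; adjusted p = 0.0569 with an estimated correlation). With p adjusted over the list alone, 10 Notch genes were higher and 2 lower, and the counts of the other lists given here did not change. Of 16 cell cycle genes 14 fell and 2 (MCM6, CCNE2) did not pass (9.1e-48). Of 9 ductal genes 6 rose, ANXA4 by 3.09-fold, KRT19 fell and 2 (CFTR, SPP1) did not pass (9.1e-04). The hypoxia and glycolysis list had 6 genes higher, 2 lower (PDK1, ADM) and 2 not past and missed the threshold (0.0516), as in the other comparisons. In this step it passed with DESeq2 size factors (0.0332), with no count filter (0.0246), with the replicate number as a block (0.0421) and without Day 9 replicate 3 (0.0314) or Day 12 replicate 1 (0.0358). It also passed without Day 0 replicate 2 (0.0331) or replicate 3 (0.0429), Day 6 replicate 1 (0.049) or replicate 3 (0.0453), Day 15 replicate 1 (0.0426) or Day 18 replicate 1 (0.0262), replicate 2 (0.048) or replicate 3 (0.0486), and ran up to 0.0794 at the preset correlation. In all, 4677 genes were higher and 4302 lower on day 12 (edgeR), and 1624 and 508 of them by at least 2-fold.

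**Figure D3:**
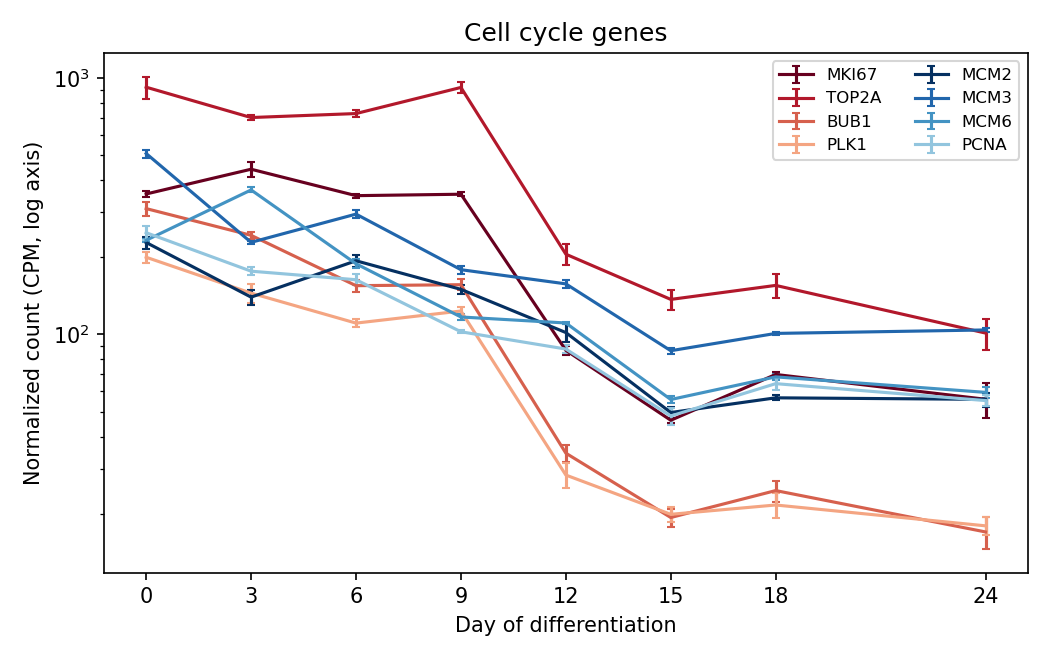
Normalized counts, as CPM (y axis, logarithmic) of 8 cell cycle genes against the day of differentiation (x axis), as means ± SD of 3 libraries. The mitotic genes MKI67, TOP2A, BUB1 and PLK1 fell from day 9 to day 12 (TOP2A from 918 to 205 CPM), and the replication genes MCM2, MCM3, MCM6 and PCNA fell from day 6 to day 9 and again from day 12 to day 15 (MCM6 from 189 to 117 and from 111 to 55.7 CPM). The mitotic genes also fell from day 12 to day 15, and MCM2, MCM3 and PCNA also fell from day 9 to day 12.

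In the step from day 12 to day 15, in which NEUROG3 rose 2.24-fold, PAX4 rose 3.04-fold to 15.0 ± 2.93 CPM, FEV 2.98-fold to 28.1 ± 6.92 and INSM1, a zinc finger factor of endocrine precursors, 1.92-fold to 62.3 ± 4.99. GCG rose 8.78-fold to 553 ± 28.9 CPM, GHRL 6.72-fold to 384 ± 40.1, and the prohormone convertase PCSK1 5.11-fold. ABCC8, a subunit of the potassium channel that couples glucose to insulin release, rose 7.04-fold to 19.0 ± 4.79 CPM. CGA, the common alpha subunit of the glycoprotein hormones, rose 35.1-fold to 33.3 ± 0.982 CPM, and the secretory protein-folding genes AGR2 and AGR3 rose 35.4-fold and 16.7-fold. The cardiac actin gene ACTC1 fell 5.28-fold and LIN28A, an RNA-binding protein of early cells, 4.19-fold.

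Of 14 endocrine progenitor genes 9 rose and 5 did not pass (camera adjusted p = 7.4e-07; adjusted p = 0.0516 with an estimated correlation). Of 9 islet transcription factor genes 7 rose, among them ETV1 (2.49-fold) and PAX6 (2.38-fold), and 2, among them MAFA, did not pass (4.7e-06). All 5 hormone genes rose (3.3e-12), and of 16 granule genes 15 rose and RAB3B did not pass (5.4e-18). The 19 Notch genes split, with 5 higher, among them HES6 (1.77-fold) and MFNG (1.67-fold), 6 lower, among them HES1 and NRARP (1.62-fold), and 8 not past, and camera did not pass (0.82). Among the 5 was DLL4, at 13.8 ± 2.01 and 20.003 ± 4.07 CPM, whose call ended without Day 15 replicate 2 (adjusted p = 0.057; 1.7e-04 to 0.057 over its alternatives). All 16 cell cycle genes fell, MCM2 by 2.05-fold, MCM6 by 1.99-fold and MKI67 by 1.87-fold (1.5e-23). When adjusted over the list alone, 11 endocrine progenitor genes were higher, 6 Notch genes were higher and 7 lower, 10 glucose sensing and beta cell genes were higher and 1 lower, 11 mitochondrially encoded genes were higher, and the counts of the other lists given here did not change. Of 12 glucose sensing and beta cell genes 7 rose, SIX3 fell and 4 did not pass (8.3e-05). Of 9 ER stress genes 6 rose, XBP1 by 2.66-fold to 271 ± 8.50 CPM and HERPUD1 by 2.41-fold, and 3 (TRIB3, DNAJB9, ERN1) did not pass (4.4e-11). Of 8 acinar genes 7 rose and CEL did not pass (4.8e-04). The mitochondrial share of counts went from 2.82% ± 0.125 to 3.41% ± 0.311, and 9 of 13 mitochondrially encoded genes rose (camera adjusted p = 0.0177, and 0.553 with an estimated correlation). At the preset correlation this list call ended without Day 15 replicate 2 (0.0837), and its adjusted p ran from 6.3e-05 to 0.0837 over the alternatives. In all, 3877 genes were higher and 3697 lower on day 15 (edgeR), and 966 and 402 of them by at least 2-fold.

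From day 15 to day 18 NEUROG3 fell 3.54-fold, and with it INSM1 (1.94-fold, to 32.0 ± 4.11 CPM), PAX4 (1.78-fold, to 8.42 ± 1.13) and RFX6 (1.66-fold, to 131 ± 5.20), while hormone genes went on rising. GHRL rose 2.11-fold to 810 ± 18.4 CPM and INS 1.86-fold to 301 ± 13.3. TPH1, the rate-limiting enzyme of serotonin synthesis in enterochromaffin cells, rose 6.85-fold to 77.8 ± 3.33 CPM, and AFP, a fetal liver and yolk sac protein, 5.75-fold to 507 ± 78.4. CGA fell 44.5-fold back to 0.749 ± 0.0771 CPM. HES6 and DLL3, of the Notch pathway, fell 2.15-fold and 2.70-fold.

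Of 14 endocrine progenitor genes 5 fell and 9 did not pass (camera adjusted p = 5.7e-05; adjusted p = 0.0861 with an estimated correlation). Of 5 hormone genes 4 rose and PYY did not pass (0.00627; adjusted p = 0.103 with an estimated correlation). GCG went from 553 ± 28.9 to 1108 ± 193 CPM and SST from 12.5 ± 2.27 to 20.4 ± 2.99. The GCG call ended with DESeq2 (log2 change 1.00, as in the edgeR fit, adjusted p = 0.396; 5.3e-37 to 0.396 over its alternatives), and the SST call ended with limma on log2(RPKM + 0.1) (0.102) and without Day 15 replicate 1 (0.0509), Day 15 replicate 3 (0.0738), Day 18 replicate 1 (0.062) or Day 18 replicate 3 (0.058), with 5.0e-08 as its lowest value. The 16 granule genes had 5 higher, among them SLC30A8 (1.93-fold) and CHGB (1.77-fold), 3 lower (VGF, CPE, RAB3B) and 8 not past (0.438). Of 7 CDK inhibitor genes CDKN2B rose 1.497-fold, CDKN1C fell 1.58-fold and 4 did not pass (0.753). The remaining one, CDKN2A, was at 4.11 ± 0.432 and 5.36 ± 0.296 CPM (edgeR adjusted p = 0.0379), and its call ended with no count filter (0.119), with limma on log2(RPKM + 0.1) (0.0514) and without Day 15 replicate 1 (0.118), Day 15 replicate 3 (0.119), Day 18 replicate 2 (0.0938) or Day 18 replicate 3 (0.0763), with 0.00509 as its lowest value. With p adjusted over the list alone, 6 endocrine progenitor genes were lower, 4 hormone genes were higher and 1 lower, and the granule and CDK inhibitor counts did not change.

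In the same step 11 of 12 mesenchyme genes rose, ACTA2 by 2.14-fold and LUM by 2.05-fold, and PDGFRA fell (camera adjusted p = 2.7e-08; adjusted p = 0.0847 with an estimated correlation). Of 16 cell cycle genes 9 rose, MKI67 by 1.51-fold, and 7 did not pass (1.1e-04; adjusted p = 0.125 with an estimated correlation). Of 9 ER stress genes 5 fell, HERPUD1 by 1.85-fold and XBP1 by 1.80-fold, and DDIT3 and TRIB3 rose (3.3e-05; adjusted p = 0.0569 with an estimated correlation). Without Day 18 replicate 1, which had 26317 genes with a count against 29159 and 28746 in the other libraries of that day, 1 ER stress gene, 3 hormone genes and 11 mesenchyme genes rose and 0 mesenchyme genes fell; counts without this library were chosen after seeing the data. The mitochondrial share of counts was 4.09% ± 0.256 on day 18, and 9 of 13 mitochondrially encoded genes rose while MT-ND1 fell 1.29-fold (0.0026; adjusted p = 0.441 with an estimated correlation). When adjusted over the list alone, 10 cell cycle genes were higher, 10 mitochondrially encoded genes were higher and 1 lower, and the mesenchyme and ER stress counts did not change. In all, 2781 genes were higher and 2654 lower on day 18 (edgeR), 5435 together, against 3133 in a fit of only the 6 libraries compared.

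Between day 18 and day 24 hormone genes and some acinar genes rose and NEUROG3 fell further, to 11.5 ± 1.83 CPM (1.71-fold). GHRL rose 2.01-fold to 1628 ± 231 CPM. The acinar elastase gene CELA3A rose 31.2-fold, from 1.55 ± 0.135 to 48.4 ± 7.85 CPM. The granule genes VGF and PCSK1N rose 2.34-fold and 2.29-fold, and SLC30A8, the zinc transporter of insulin granules, 1.58-fold. The glucose transporter gene SLC2A1 rose 1.60-fold to 79.1 ± 7.87 CPM. LIN28A fell 4.35-fold to 7.22 ± 0.772 CPM, and the receptor genes KIT and FLT1 fell 2.92-fold and 2.81-fold.

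All 5 hormone genes tested rose (camera adjusted p = 8.3e-05), 3 of 6 without Day 18 replicate 1. GCG went from 1108 ± 193 to 1914 ± 323 CPM and SST from 20.4 ± 2.99 to 31.3 ± 6.78. The GCG call (log2 change 0.79) ended with DESeq2 (0.77, adjusted p = 0.521), with limma on log2(RPKM + 0.1) (0.111) and without Day 18 replicate 3 (0.0529), Day 24 replicate 1 (0.0636) or Day 24 replicate 2 (0.057), with 2.2e-22 as its lowest value. The SST call ended with that limma setting (0.18) and without Day 18 replicate 1 (0.0723), replicate 2 (0.105) or replicate 3 (0.0606), Day 24 replicate 1 (0.136) or Day 24 replicate 2 (0.119), with 4.9e-06 as its lowest. CHGA went from 5928 ± 193 to 9418 ± 1681 CPM, a call that ended without Day 24 replicate 1 (0.0597; 7.2e-13 to 0.0597 over its alternatives). Of 16 granule genes 8 rose, RAB3B fell and 7 did not pass (0.0203; adjusted p = 0.421 with an estimated correlation), a list call that ended without Day 18 replicate 2 (0.31) or Day 24 replicate 1 (0.117), with 0.00186 as its lowest value. Of 12 glucose sensing and beta cell genes SLC2A1 and SIX2 rose, and 3 rose without Day 18 replicate 1 (0.0478; adjusted p = 0.218 with an estimated correlation). This list call ended without Day 0 replicate 2 (0.0502), Day 18 replicate 2 (0.179), Day 18 replicate 3 (0.0893) or Day 24 replicate 1 (0.119), with 0.00597 as its lowest value. Of 9 islet transcription factor genes 2 fell and 7 did not pass (0.752; median log2 change -0.06, mean 0.01). They were ISL1, at 24.6 ± 2.17 and 20.9 ± 1.99 CPM, and ETV1, at 28.1 ± 1.83 and 22.4 ± 1.98 CPM. Neither passed without Day 18 replicate 1 (adjusted p = 0.266 and 0.053) or without Day 24 replicate 2 (0.117 and 0.068), and ISL1 did not pass without Day 18 replicate 3 (0.0544), without Day 24 replicate 3 (0.177), with no count filter (0.104) or with limma (0.0649 and 0.0798). The lowest values were 0.0186 for ISL1 and 8.7e-04 for ETV1. With p adjusted over the list alone, 9 granule genes were higher and 3 lower, 1 islet factor was higher and 2 lower, and the hormone and glucose sensing counts did not change.

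In the same step 7 of 14 endocrine progenitor genes fell and 7 did not pass (camera adjusted p = 0.00291; adjusted p = 0.204 with an estimated correlation). Of 12 pluripotency genes 6 fell, UTF1 rose and 5 did not pass (1.6e-07). UTF1 had 29 against 2 counts, a ratio of 10.004 (95% counting interval 2.53 to 86.5; log2 change 3.125, 2.451 without Day 18 replicate 1), and its call ended with limma on log2(RPKM + 1) (0.313; 2.8e-04 to 0.313 over its alternatives). Of 8 acinar genes 4 rose, PRSS1 fell and 3 did not pass (1.3e-05). Of 16 cell cycle genes 11 fell, TOP2A by 1.53-fold, and 5 did not pass (2.4e-06; adjusted p = 0.0784 with an estimated correlation). When adjusted over the list alone, 8 endocrine progenitor genes were lower, 1 pluripotency gene was higher and 9 lower, 5 acinar genes were higher and 1 lower, 12 cell cycle genes were lower and 9 mitochondrially encoded genes were higher. By the test over all genes without Day 18 replicate 1, 5 in place of 7 endocrine progenitor genes and 7 in place of 6 pluripotency genes fell. In that fit 3 in place of 4 acinar genes and 7 in place of 8 granule genes rose, and 11 cell cycle genes fell as before. The mitochondrial share of counts was 4.51% ± 0.0846 on day 24. Mitochondrially encoded genes rose in 8 of 13 cases, and in 4 without Day 18 replicate 1 (9.3e-04; adjusted p = 0.417 with an estimated correlation). In all, 2449 genes were higher and 2649 lower on day 24 (edgeR), 5098 together, against 2862 without Day 18 replicate 1 and 2395 in a fit of only the 6 libraries compared. The share that was higher depended on the setting, at 48.0% here, 41.1% of 5272 genes with DESeq2 size factors and 54.7% of 4541 with limma on log2(RPKM + 1), and by at least 2-fold 400 genes were higher and 225 lower.

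Over the whole course, day 24 against day 0, the hormone genes went from near 0 to high levels. INS was at 1 count on day 0, and its ratio was 52545 (95% counting interval 9431 to 2075500). The counts of INS (1) and GCG (6) on day 0 all lay in Day 0 replicate 1, and without it their rises were at least 1885-fold and 8750-fold. GHRL rose 2806-fold and SST 363-fold (log2 change 8.504, 9.376 without Day 0 replicate 1). PDX1 rose from 0 counts, at least 610-fold, and CHGA rose 147-fold. NEUROG3 was 9.46-fold and HES1 4.09-fold above day 0. POU5F1 fell 10285-fold to 0.157 ± 0.0386 CPM and NANOG 1813-fold (log2 change -10.82, -11.42 without Day 24 replicate 2), and the zymogen granule gene CUZD1 fell from 31.1 ± 2.79 CPM to 0 counts, at least 633-fold. BUB1 fell 18.199-fold, CDC20 11.6-fold and PLK1 11.1-fold. DCN, a matrix proteoglycan of connective tissue, rose 88.2-fold to 120 ± 16.4 CPM and the collagen gene COL3A1 24.9-fold to 2074 ± 289.

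All 12 pluripotency genes fell (camera adjusted p = 5.2e-37), all 16 cell cycle genes fell (1.4e-28) and all 5 hormone genes rose (1.7e-06). Of 12 mesenchyme genes 10 rose and PDGFRB and THY1 fell (7.3e-04; adjusted p = 0.295 with an estimated correlation). All 11 pancreatic progenitor genes rose (7.9e-10; adjusted p = 0.0623 with an estimated correlation), as did all 7 CDK inhibitor genes (0.015; adjusted p = 0.0847 with an estimated correlation). Of 9 ductal genes 7 rose and KRT7 and SPP1 fell (3.2e-05). Of 8 acinar genes 5 rose, BHLHA15 fell and 2 (CEL, RBPJL) did not pass (5.2e-04; adjusted p = 0.0733 with an estimated correlation). Of 12 nuclear oxidative phosphorylation genes 9 fell, CYCS by 4.45-fold, and 3 did not pass (camera adjusted p = 0.0408, and 0.45 with an estimated correlation). At the preset correlation this list call ended without Day 24 replicate 1 (0.0527), and its adjusted p ran from 2.6e-04 to 0.0527 over the alternatives. The counts of these 9 lists were the same when adjusted over the list alone. In all, 9045 genes were higher and 7897 lower on day 24 (edgeR).

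**Figure D4:**
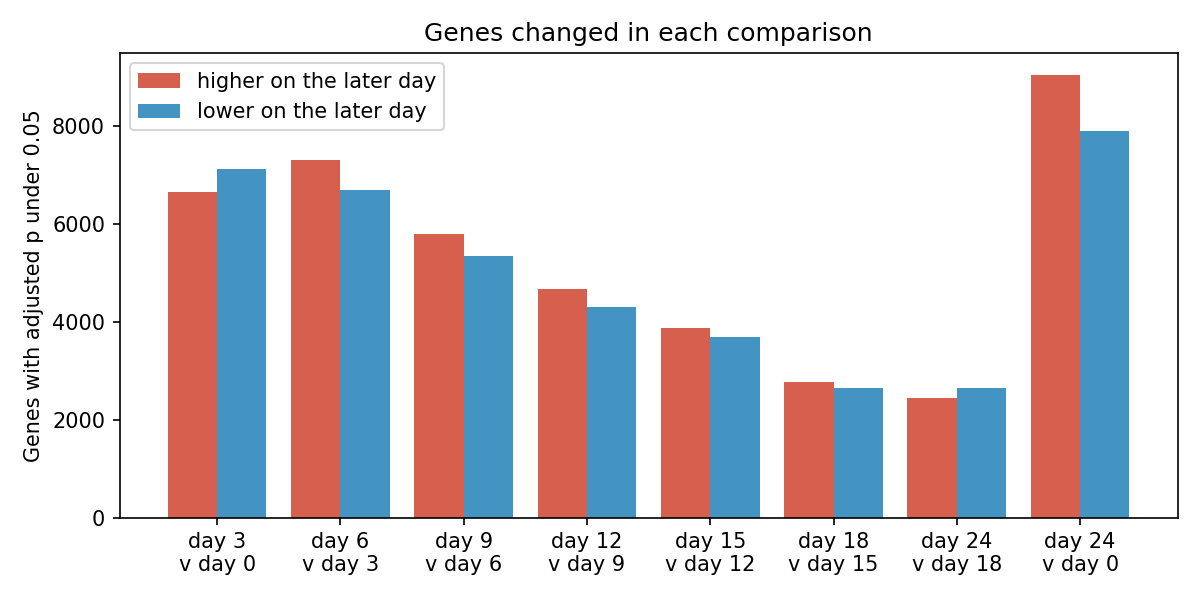
Number of genes with an edgeR adjusted p under 0.05 (y axis) in each comparison of days (x axis), with bars for genes higher and for genes lower on the later day. The number fell from 14013 genes (day 6 against day 3) to 5098 (day 24 against day 18) among neighbouring days, and was 16942 for day 24 against day 0.

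Markers of some other cell types rose as well. TPH1 rose from 0.709 ± 0.159 CPM on day 12 to 11.4 ± 1.33 on day 15 (16.2-fold) and 117 ± 11.9 on day 24, and SLC18A1, a vesicular monoamine transporter, from 0 counts on day 0 to 23.9 ± 3.48 CPM on day 24, at least 152-fold. Of the 8 enterochromaffin genes, 3 of which pancreatic cells are also known to express, 6 rose from day 12 to day 15 (camera adjusted p = 1.7e-09), 5 rose and CHRNA3 fell to day 18 (1.6e-04), and 5 rose and DDC fell to day 24 (0.00267; adjusted p = 0.0569 with an estimated correlation; 5 and 0 without Day 18 replicate 1). Of the 12 liver genes, 2 of which pancreatic cells also express, 6 rose and SERPINA1 fell from day 12 to day 15 (2.9e-04; adjusted p = 0.0847 with an estimated correlation). From day 18 to day 24, 5 liver genes rose and APOA2 and TF fell (0.00489; adjusted p = 0.161 with an estimated correlation), and against day 0, 11 rose and AHSG fell (1.2e-18). On day 24 AFP was at 1096 ± 68.3 CPM, TTR at 990 ± 158 and albumin (ALB) at 6.15 ± 0.219. The intestine and stomach list, with 2 of its 13 genes also expressed in pancreas, had 5 genes higher and 5 not past from day 18 to day 24 (7.2e-05) and 8 higher and 2 lower, among them BARX1, against day 0 (4.5e-06). Its sucrase gene SI was at 42.8 ± 1.48 CPM and TFF1 at 4.26 ± 0.781 on day 24. For the neural list, 3 of whose 10 genes pancreatic endocrine cells also express, no comparison after day 3 against day 0 passed, and of the mesenchyme list 1 of 12 genes and of the endothelium and blood list 0 of 8 were counted as pancreatic too. None of these 6 lists shared a gene with another list. With p adjusted over the list alone, 6 enterochromaffin genes were higher and 2 lower from day 18 to day 24, 6 liver genes were higher and 2 lower both in that step and from day 12 to day 15, and the other counts given for these lists did not change.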

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

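The counts of list members without Day 18 replicate 1 or Day 0 replicate 2 were chosen after seeing the data, and the other alternatives were set beforehand. The number of genes past the edgeR test stayed within 1.5 times the reported number in all 8 comparisons with DESeq2 size factors, no count filter, the DESeq2 test, and limma on log2(RPKM + 1) or log2(RPKM + 0.1). Requiring at least a 2-fold change as well, a stricter rule by construction, left 5954, 5836, 3268, 2132, 1368, 904 and 625 genes in the 7 steps from day 3 against day 0 to day 24 against day 18, and 9362 for day 24 against day 0. Of these, 2494, 3570, 1765, 1624, 966, 472 and 400 were higher and 3460, 2266, 1503, 508, 402, 432 and 225 lower in the 7 steps, and 5453 higher and 3909 lower for day 24 against day 0. A fit of only the 6 libraries of the days compared, which has fewer samples to estimate the spread, gave 3133 genes for day 18 against day 15 and 2395 for day 24 against day 18, against 5435 and 5098 with all libraries. It also takes the spread from those days alone, and replicates differed more on some days than on others. Their Pearson correlations were 0.9976 to 0.9978 within day 9 and 0.992 to 0.995 within day 18. Which of these differences lowered the numbers of genes was not tested. Leaving out each library of the days compared gave 12978 to 13583 genes for day 3 against day 0, 13022 to 13581 for day 6 against day 3, 9939 to 10161 for day 9 against day 6, 7494 to 8579 for day 12 against day 9, 6317 to 7155 for day 15 against day 12, 4027 to 5916 for day 18 against day 15, 2862 to 7273 for day 24 against day 18 and 16267 to 16927 for day 24 against day 0. The extremes of 24 against 18 came without Day 18 replicate 1 (2862) and without Day 18 replicate 2 (7273), and the cause was not tested beyond the comparison of the day 18 libraries given under the other observations. For genes changed over the 8 days, the F test gave 20415 to 20722 without 1 library, against 20246 with all libraries. The count filter was applied anew in each fit without 1 library, so the genes tested were not the same. Without Day 18 replicate 1, for example, 6 hormone genes were tested in place of 5. Of the 232 list tests, 112 passed as reported, 41 with an estimated correlation in place of the preset 0.01 (the cause was not tested), and 179 with fry, which asks a different question; without 1 library 106 to 115 passed, and no list that passed in both fits turned its direction. With DESeq2 size factors 113 list tests passed, among them all 112, and with no count filter 130, with 7 lost and 25 gained. Of the named genes' calls, 2192 stayed, 56 were lost and 2 were gained in fits without 1 library. Under the other alternatives applied to them 2528 stayed, 92 were lost and 2 were gained, 63 of the losses from the 2-fold rule. None of these calls changed direction. The fit of only the 6 libraries of the days compared was not applied to the named genes. Without Day 18 replicate 1, 3 in place of 5 hormone genes rose and 0 in place of 2 islet transcription factor genes fell from day 18 to day 24, and the cause was not tested. The replicate numbers did not pair the libraries: of 84 pairs with the same number 17 had deviations correlated above 0.1, the median was -0.0132 against -0.0137 for pairs with different numbers, and 7 of 24 libraries lay closest to their own number. Within single comparisons, 2 of 3 pairs were above 0.1 for day 18 against day 15 (-0.0636 to 0.306), 1 of 3 for day 24 against day 18 (0.0499 to 0.230) and 0 of 3 in each of the other 6, so that in none were all 3 pairs above 0.1. With the number as a replicate block, 13725, 13993, 11104, 8899, 7539, 5350 and 5012 genes passed in the 7 steps, 16865 for day 24 against day 0 and 20181 over the 8 days. The replicate block changed no named gene's call, and 113 list tests passed, with 2 lost (endothelium and blood for day 3 against day 0, adjusted p = 0.0783, and definitive endoderm for day 9 against day 6, 0.0608) and 3 gained. Depth limited low genes most on day 0, where 3 counts in Day 0 replicate 2 (8700062 counts in all) equalled 0.345 CPM.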

Other observations

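The genes in the next paragraphs and the tests on NEUROG3 between day 9 and day 12, on other splits of the libraries, and of the day 15 turn with other size factors, on genes that fell and then rose, or without single libraries were chosen after the results were seen. Single cell cycle genes fell in several steps. The proliferation marker MKI67, the kinase PLK1 and the anaphase activator CDC20 changed by -2.02 ± 0.07, -2.12 ± 0.08 and -2.04 ± 0.07 on the log2 scale from day 9 to day 12 (edgeR adjusted p = 2.4e-17, 8.5e-17 and 7.0e-18). The replication genes MCM3, PCNA and MCM6 changed by -0.18 ± 0.05 (0.0029), -0.22 ± 0.06 (0.00398) and -0.08 ± 0.05 (0.206) in that step, and in the next, from day 12 to day 15, these genes changed by -0.87 ± 0.05, -0.87 ± 0.06 and -0.99 ± 0.05 (3.0e-13, 2.7e-11 and 3.8e-14). MKI67 also fell in that next step, by -0.91 ± 0.07 (2.3e-10), and replication genes had fallen earlier, from day 6 to day 9, MCM5 by -0.81 ± 0.07 (1.3e-10), MCM3 by -0.72 ± 0.05 (1.35e-12) and the cyclin gene CCNE2 by -0.82 ± 0.12 (3.1e-06), so these genes show no single order of mitotic and replication genes, and a difference between the groups was not tested. From day 15 to day 18, PCNA rose by 0.42 ± 0.06 (1.1e-05) and MKI67 by 0.59 ± 0.07 (7.1e-07), while PLK1 (0.12 ± 0.09, 0.349) and CDC20 (0.08 ± 0.07, 0.448) did not pass.

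Day 15 stood apart from its neighbours for genes of several kinds. NDRG1, a stress-responsive gene, went from 116 ± 5.84 CPM on day 12 to 299 ± 10.03 on day 15 and 174 ± 25.8 on day 18, SHH, a hedgehog ligand, from 34.4 ± 3.48 to 123 ± 5.87 and 75.1 ± 9.12, and CPE, a carboxypeptidase that trims prohormones, from 416 ± 8.81 to 987 ± 48.4 and 571 ± 39.5. Other genes made the opposite turn. SOX9, a progenitor and duct factor, changed by -1.32 ± 0.08 and then by 0.99 ± 0.08 (edgeR adjusted p = 7.6e-13 and 4.2e-10), the bicarbonate transporter gene SLC4A4 by -1.05 ± 0.12 and 1.09 ± 0.12 (4.71e-07 and 6.55e-07), and the epithelial keratin gene KRT18 by -1.43 ± 0.07 and 0.67 ± 0.06 (6.35e-15 and 1.15e-08). HES1 made the same turn as SOX9. The pancreatic progenitor list, which holds SOX9, did not turn this way as a whole, with 6 of 11 genes higher and 2 lower on day 15 than on day 12, and 4 higher and 4 lower on day 18 than on day 15 (6 and 3, then 6 and 4, when adjusted over the list alone).

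In all, 1357 genes rose from day 12 to day 15 and fell to day 18, against 480 from independent lists of the same sizes. Another 1209 fell and then rose, against 480. In both steps 426 rose, against 503, and 191 fell, against 458. Noise of the day 15 libraries, which both steps share, could give such turns, but the excess remained when the rise was called with 2 day 15 libraries and the fall with the other one, at 2.665 times independent lists at the lowest (863 against 324 genes). That test, which assumes that a lone library varies like those of other days, was added after the turn counts were seen. A wrong scale of the day 15 libraries shifts all genes the same way and is argued against as the whole cause, since genes that fell and then rose were also in excess, at 2.30 times independent lists at the lowest when the steps used different day 15 libraries (420 against 183 genes). DESeq2 size factors, with which 99.6% of the 1357 genes kept both calls, decide nothing, since they hardly differed from TMM here. Without 1 library 1043 to 1444 genes turned. Simulated unchanged groups gave at most 0 such genes in 10 runs, which decides nothing, since they hold no real changes, and a difference in handling of the 3 day 15 libraries cannot be told apart from the day, so that a passing state of the cells on day 15, which may go with the highest level of NEUROG3, stays an untested hypothesis. An excess of genes up then down was not confined to day 15. Such genes numbered 3870 around day 3 (against 2079.5 from independent lists), 2079 around day 6 (1830) and 1311 around day 9 (1162). They numbered 672 around day 12 (against 807) and 434 around day 18 (344). Around days 6, 9 and 18, genes that rose in both steps were also in excess, at 2291 (against 1977), 1774 (1263) and 576 (318). The excess around those days was therefore not particular to turns. Around day 3, as around day 15, fewer genes rose in both steps than from independent lists (1213 against 2274).

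NEUROG3 was lower on day 12 than on days 9 and 15, by -0.37 ± 0.13 against day 9 (edgeR adjusted p = 0.0343). With DESeq2 size factors the change was -0.34 ± 0.14 (0.0535), so the call ended through a small shift and a slightly larger error. These factors hardly differed from TMM, so this alternative cannot decide on scaling, which stays open. Without Day 12 replicate 2 it was -0.23 ± 0.13 (0.184), between 1 and 2 standard errors below 0, so that this library may account for part of the dip. The adjusted p ran from 4.6e-04 to 0.184 over its alternatives, and a decline between a pair of waves of NEUROG3 cannot be told apart from either explanation with 3 libraries per day. No biological explanation was tested.

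The day 18 libraries stood apart from one another. Day 18 replicate 1 had 26317 genes with a count and the others 29159 and 28746, and with all libraries thinned to 8700062 counts it still had 22669 against 23814 and 23382. On an axis from day 15 (0) to day 24 (1) over 1918 genes, the day 18 libraries lay at 0.537, 0.595 and 0.573, a range 1.36 times the larger of the ranges of day 15 and day 24, so unequal progress along the course stays open. The axis genes were chosen by their change between day 15 and day 24 in these same libraries. That choice can narrow the ranges of those days, while day 18 took no part in it. If low complexity of replicate 1 set its place, its gap to replicate 2 could shrink over abundant genes, and the gap was 1.33 times as wide over the 303 axis genes with at least 10 CPM, which goes against low complexity. This does not decide, because a gap between 2 single libraries is set against few others: it was 0.0578 against ranges of 0.0427 within day 15 and 0.0145 within day 24 over all axis genes, and 0.0771 against 0.0363 and 0.0521 over the abundant ones. No biological explanation was tested.

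For the counts of changed genes, 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 13794 genes for day 3 against day 0 (highest other split 3), 14013 for day 6 against day 3 (15), 11144 for day 9 against day 6 (1), 8979 for day 12 against day 9 (0), 7574 for day 15 against day 12 (0), 5435 for day 18 against day 15 (1761), 5098 for day 24 against day 18 (1752) and 16942 for day 24 against day 0 (0), each as 1 of 10 splits. The other splits with 1761 and 1752 genes both parted Day 18 replicate 2 from replicates 1 and 3 of that day, and the cause was not tested. Over the 8 days, 1 of 40 groupings, the real one, gave as many as 20246 genes, the highest other giving 420. A share of 1 of 40 is the smallest that this test could give. It argues against a random grouping of the libraries, and it cannot tell the day from a difference in handling between days.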
